A study of Mus musculus with 14 samples.

How the data were processed

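The BaCl2 count values are whole-number read counts per gene and library as deposited, for 56953 genes, of which 23999 were at 0 in every library. The glycerol signal values are the authors' normalized counts per gene and library as deposited, for the genes they kept, with a lowest mean of 7.79, 83 values at 0 and no mitochondrially encoded gene listed. At most 50.1% of the low glycerol values fell on whole steps (tolerance 0.1), so no counts could be recovered from them and the depth is unknown. The log2 fold changes and their standard errors in the files were made by the authors, SMA against WT, positive where SMA is higher. The p-values and adjusted p-values in the files were likewise made by the authors per the file headers, and both were used here only to set beside the tests made here. Another 6 columns of the BaCl2 table hold z-scores of the counts of 4026 genes per the file headers and values, and were not used. The labels name fastp, Salmon, featureCounts and DESeq2 without versions or roles. The aligner, genome build, annotation and which of the tools made the counts are not given in the sources used here. The labels name RNA extraction with the RNeasy Micro kit, poly(A) selection and the NEBNext Ultra II Directional kit from 50 ng of total RNA. Reads were not analysed here.

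The work was done with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Comparisons, tests, gene lists and alternatives were fixed before the data were examined, except where an alternative or test is said to have been added later. After BaCl2, counts were scaled with TMM factors (0.953 to 1.05), low genes were removed with filterByExpr, and SMA was compared with WT by the quasi-likelihood F test of edgeR. CPM values are TMM-scaled counts per M of the library (M, mega). The library totals of 97.7 M counts or more give a gene at 1 CPM at least 97.7 counts. Depth limits the genes named that lie far below that, such as Adipoq after BaCl2 (mean 0.159 CPM in SMA and 0.153 CPM in WT libraries) and Hal in the WT libraries (0.232 CPM). The 10 highest genes hold 9.85% to 13.6% of the counts of a library. The plan had assumed counts for glycerol too. As its values were normalized already, log2(value + 1) was fitted with limma with a mean-variance trend. All p-values were adjusted by the method of Benjamini and Hochberg, and genes passed at an adjusted p under 0.05. The sign is SMA minus WT throughout, and glycerol minus BaCl2 for the difference. The difference of the genotype effect between the injuries was tested on 13960 genes fitted in both, matched by gene identifier, as the difference of the log2 fold changes over its standard error (a z test). The 14 libraries were not fitted jointly, as the tables were normalized separately and only one holds counts.

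Gene lists were written from general knowledge of muscle stroma and its cell types, 31 lists with 609 symbols, of which 603 occur in the BaCl2 table and 545 in the glycerol table. Lists with at least 5 members tested were tested with cameraPR of limma at its preset correlation of 0.01, and again with a correlation estimated from the data. Members were also adjusted over their list alone. The level of a list in a library is the mean of its members' log2 values relative to the WT mean, and an exact permutation test of these levels over all relabelings was added after the data were seen. For the difference between injuries it runs over 1400 relabelings, with a smallest possible p of 0.00143. These shuffle the genotype within both injuries, so a genotype effect that the injuries share makes a difference harder to detect. Calls shared by the injuries were tested with Fisher's exact test against independence. Smn1 was also tested by exact permutation of its values.

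Genes were named by rule. In each comparison the 8 largest changes per direction were named among genes with an adjusted p under 0.05, a mean of at least 1 CPM (after BaCl2) or above the median mean (after glycerol), and every SMA library on the same side of every WT library, with predicted genes skipped. Up to 4 passing members of each list of biology were added by smallest p, with Smn1, Pdgfra, Pparg, Cebpa, Lpl, Fabp4, Adipoq and Plin1 always named. For the difference between injuries 5 genes per direction were named. Some further members are named where they show what a list holds, and a few genes that the rule names are not reported here. Reference gene types from GENCODE vM21 served only to name pseudogenes and to count chromosomes, and no coordinates are given because the build of the deposited tables may be another.

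Simulated data with known changes were run through the same steps. At folds of 1.5, 2 and 4, edgeR recovered 41.8%, 61.2% and 80.3% of changed genes with 6.87% of its calls false, and DESeq2 46.3%, 68.7% and 86.4% with 19.3% false. On values like those after glycerol limma recovered 70.1%, 85.1% and 98.5% with 4.52% false. For the difference between injuries, the z test recovered 68.2%, 85.7% and 100% with 24% false, and a t reference with Satterthwaite degrees of freedom 60.6%, 79.4% and 93.9% with 7.88% false. With no gene changed the calls were 2 for edgeR, 0 for limma, 7 for z and 0 for t. Of 200 unchanged lists 0 were called in the simulation of either injury. The simulated genes varied independently, so this does not check camera on lists whose members move together. In the data the estimated correlation reached 0.863, for the interferon response list after glycerol.

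The alternatives fixed in advance were DESeq2, RLE and upper-quartile factors, no filter and a stricter filter (10 counts) after BaCl2, pseudocounts of 0.1 and 5 and only genes above the median mean after glycerol, a replicate block, each library left out in turn, an absolute log2 fold change of at least 1, other thresholds for the shared calls, and fry for the lists. Those added after the data were seen were SMA libraries 1 and 2 left out together after BaCl2, the macrophage list level as a covariate, upper-quartile rescaling of the glycerol values, the t reference, the shared calls without immune lists and the permutation of list levels. No 2 library columns were identical.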

Results

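Fibro-adipogenic progenitors (FAPs) are mesenchymal stromal cells of skeletal muscle that can give rise to fat and to fibrous tissue. They were sequenced from the injured TA muscle of mice labelled SMA, read here as spinal muscular atrophy, and of wild-type (WT) mice. The cells were taken 3 days after injury by MACS, a magnetic sort of antibody-labelled cells whose antibodies the labels do not name, and their RNA was extracted without culture. The injury was made with BaCl2, a salt that kills muscle fibres and is followed by regeneration, or with glycerol, which is followed by regeneration with more fat. After BaCl2 there were 3 SMA and 3 WT libraries, and after glycerol there were 4 SMA and 4 WT libraries, 14 in all. The series asks whether FAPs of SMA muscle lean towards fat formation by themselves, so SMA was compared with WT within each injury, and the genotype effect was then compared between the injuries. The BaCl2 libraries held 97.7 M to 136 M counts (M, mega). The glycerol values were deposited after normalization, with sums of 71.4 M to 76.6 M per library, and the depth behind them is unknown. The labels also use the injury as the batch, so injury and batch cannot be told apart. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

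Smn1, the mouse gene for the survival motor neuron protein, was lower in the SMA libraries after both injuries. After BaCl2 it was at 9.995 to 11.96 CPM (counts per M of the library; mean 11.1, n = 3) in SMA and 15.34 to 17.15 CPM (mean 16.1, n = 3) in WT libraries, which is 68.8% of the WT mean. After glycerol it was at 745 ± 75.9 normalized counts (SD, n = 4) in SMA and 1084 ± 113 normalized counts (n = 4) in WT libraries, or 68.7%. Every SMA library lay below every WT library of its injury. The log2 fold change was -0.54 after BaCl2 (SE 0.09, edgeR adjusted p = 0.0131) and -0.54 after glycerol (SE 0.10, limma adjusted p = 0.0364). The two-sided exact permutation p was 0.1 after BaCl2, the smallest that 3 against 3 libraries allow, and 0.0286 after glycerol, the smallest that 4 against 4 allow. The adjusted p of Smn1 was above 0.05 after BaCl2 without SMA library 2 (0.0707), WT library 2 (0.0752) or WT library 3 (0.067), and after glycerol it was above 0.05 (0.0548 to 0.113) without each library in turn except SMA library 3 (0.0217). The labels do not name the SMA allele, so Smn1 checks the genotype labels only if the reads counted cover the altered part of the gene.

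The rest of the SMN complex and its Sm proteins, which assemble the splicing machinery, moved little. Of 17 members tested after BaCl2, 0 were higher, 1 (Smn1) was lower and 16 did not pass, with the same count when adjusted over the list alone, and camera gave an adjusted p = 0.619. After glycerol 0 of 18 were higher, 1 (Smn1) was lower and 17 did not pass, with 4 lower when adjusted over the list alone. Here Snrpd2 stood at -0.22, Snrpd1 at -0.19 and Snrpd3 at -0.25 on the log2 scale with no pass over all genes. The glycerol list was lower by camera, with a median log2 fold change of -0.12 (adjusted p = 0.00381), and adjusted p = 0.401 with an estimated correlation.

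**Figure D1:**
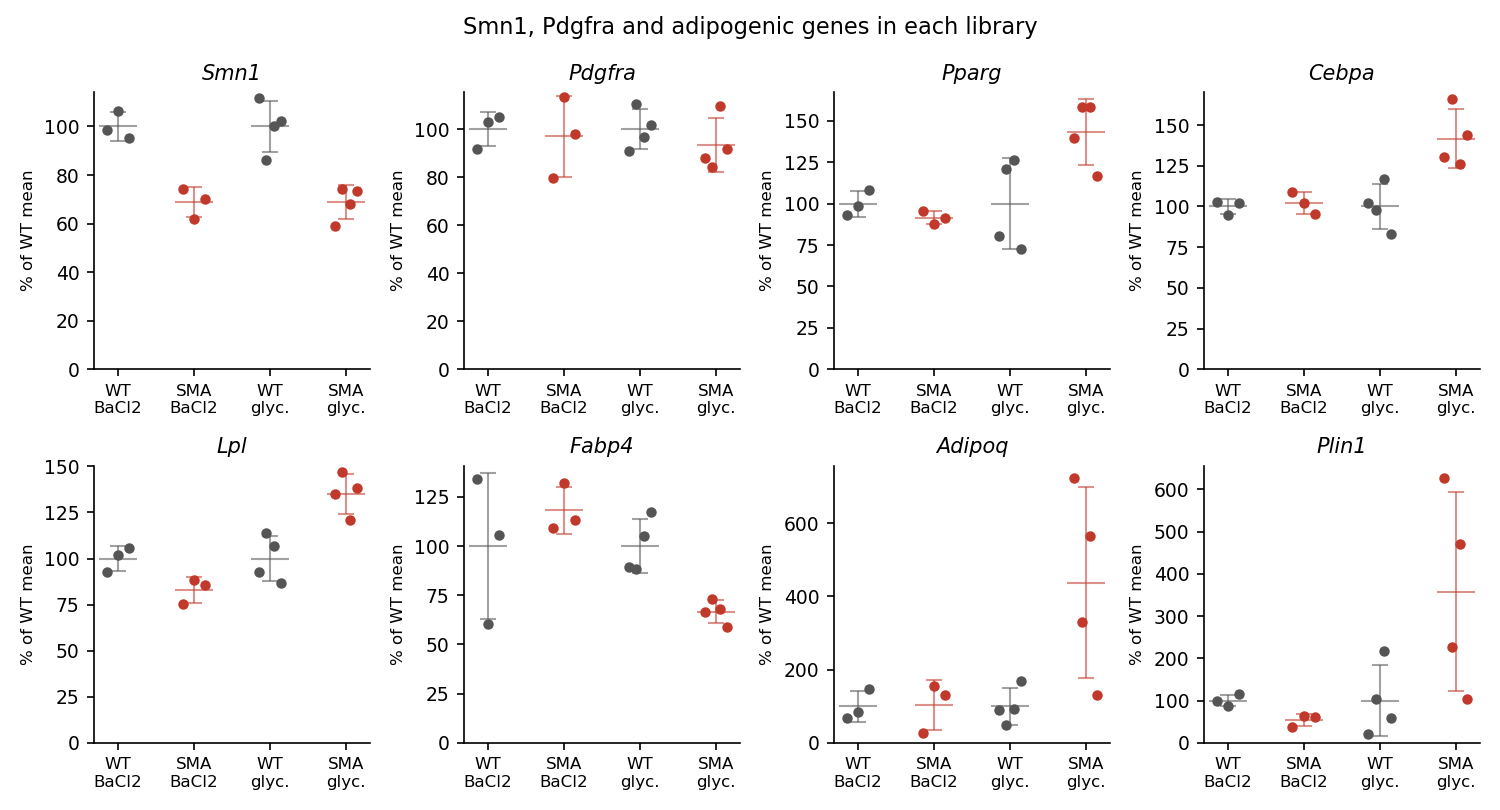
Level of Smn1, Pdgfra and 6 adipogenic genes in each library, as a percentage of the WT mean of the same injury (y axis), for WT (grey) and SMA (red) libraries after BaCl2 (n = 3 per genotype) and glycerol (n = 4); dots are libraries, the horizontal line is the mean and the bar is the SD. Smn1 lies at 68.8% and 68.7% of the WT mean, and Adipoq and Plin1 spread widely between the SMA libraries after glycerol.

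After BaCl2, the SMA libraries had more transcript of genes that macrophages express, and less of several collagen genes and of the FAP markers Vcam1, Ly6a and Lum. Apoe, the lipid carrier apolipoprotein E, rose from 598 ± 28.7 CPM in WT to 1403 ± 180 CPM in SMA (log2 fold change 1.23, SE 0.09, n = 3 each, adjusted p = 0.00164). Acod1, the itaconate-making enzyme of activated macrophages, rose from 3.29 ± 0.179 to 12.1 ± 2.46 CPM (1.87, SE 0.15, adjusted p = 0.00226). Among the largest rises were also Arg1, the arginase of macrophages in repairing tissue (2.42, SE 0.46, adjusted p = 0.0196), and Serpinb2, an inhibitor of plasminogen activators (1.95, SE 0.29, adjusted p = 0.00827). Further large rises, of Hal (5.54, SE 1.02), Pianp (4.32, SE 0.94), Rps18-ps3 (3.12, SE 0.62), Rps18-ps5 (2.65, SE 0.51) and Tdg-ps2 (2.28, SE 0.45), rested on SMA libraries 1 and 2, and that of Pianp was 2.51 without SMA library 1. Hal, histidine ammonia-lyase, stood at 16.0 and 15.9 CPM there, at 0.51 CPM in SMA library 3 and at 0.205 to 0.251 CPM in the WT libraries. The Rps18 and Tdg copies are near-identical to their parent genes, so their counts are uncertain.

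The falls after BaCl2 were smaller. Rspo2, a secreted amplifier of Wnt signalling, fell by 1.46 (SE 0.30, adjusted p = 0.0264), and Draxin, a secreted guidance protein that also acts on Wnt, fell from 30.9 ± 4.27 to 15.5 ± 1.97 CPM (log2 fold change -0.99, SE 0.12, n = 3 each, adjusted p = 0.00471). Astn2 fell by 1.01 (SE 0.13, adjusted p = 0.00604). Ankef1 (-1.36), Ptprv (-1.25), Bend5 (-1.06), Lrrc55 (-0.99) and Gdpd2 (-0.96) were also lower, each at a mean of 1.12 CPM or less in SMA except Lrrc55 (1.24 CPM).

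In total edgeR called 863 of 20119 genes after BaCl2, 549 higher and 314 lower, and 169 of them had an absolute log2 fold change of at least 1 (161 higher, 8 lower). The genotypes did not overlap at 25.3% of the genes tested, where chance gives 10%. The authors' deposited table calls 1693 genes (951 higher, 742 lower), of which 780 were also called here, and its log2 fold changes correlate with those here across genes at 1. The count rested on single libraries: it was 559 without SMA library 1, 145 without SMA library 2, 1577 without SMA library 3, 663 without WT library 1, 163 without WT library 2 and 41 without WT library 3. Of the 16 genes named for the size of their change, 2 (Acod1 and Draxin) passed with each library left out in turn, and of 38 passing genes named from the lists 3 did (Apoe, C3ar1 and Spp1). With SMA libraries 1 and 2 both left out, edgeR called 108 genes, on the assumption that the lone SMA library varies like the WT libraries.

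Genes of fat formation moved in different directions after BaCl2. Of 23 adipogenic transcription factors tested, 0 were higher, 2 were lower and 21 did not pass, and adjusted over the list alone 1 was higher and 5 were lower. Ebf1 fell by 0.40 (adjusted p = 0.0095) and Cebpd, an early factor of adipocyte differentiation, fell by 0.47 (adjusted p = 0.0175). Pparg, the master regulator of adipocytes, stood at -0.13 (adjusted p = 0.459) and Cebpa at 0.03 (adjusted p = 0.874). The list was lower by camera, with a median of -0.15 (adjusted p = 0.0028), and adjusted p = 0.785 with an estimated correlation. Of 31 genes of adipocytes and lipid storage, 4 were higher, 0 were lower and 27 did not pass, and adjusted over the list alone 6 were higher and 5 lower. The 4 that rose were Apoe, the lipid droplet coat gene Plin2 (0.54), the fatty acid carrier gene Fabp5 (0.52) and the fatty acid transporter gene Cd36 (0.85), all of which macrophages express too. Other genes of the list did not pass, with Adipoq at 0.07 (adjusted p = 0.972), Plin1 at -0.89 (adjusted p = 0.0774), Fabp4 at 0.24 (adjusted p = 0.623) and Lpl at -0.27 (adjusted p = 0.0846). In the authors' deposited table Lpl passes as lower (-0.25, adjusted p = 0.0221). As a whole this list did not pass camera (median 0.05, adjusted p = 0.645).

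Some FAP markers and matrix genes were lower after BaCl2, and most of either list did not pass. Of 25 FAP markers, 0 were higher, 3 were lower and 22 did not pass, with 10 lower when adjusted over the list alone. Vcam1 fell by 0.47, Ly6a, which encodes the Sca-1 antigen, by 0.50 and the proteoglycan gene Lum by 0.33, while Pdgfra, the defining FAP receptor, stood at -0.04 (adjusted p = 0.889). Of 32 genes of fibrillar matrix and myofibroblasts, 2 were higher, 7 were lower and 23 did not pass, and adjusted over the list alone 3 were higher and 14 lower. The falls included Col6a2 (-0.54), Col6a1 (-0.53), Col3a1 (-0.49) and Col1a2 (-0.44), and the rises were osteopontin, Spp1 (0.88), and Tgfbi (0.47), both also made by macrophages. Camera gave an adjusted p = 0.00313 for the FAP markers (median -0.11) and 5.67e-05 for the matrix genes (median -0.22), and for both adjusted p = 0.785 with an estimated correlation.

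Markers of macrophages and monocytes were the gene group with the most changes after BaCl2. All 24 tested had a positive fold change, 19 were higher, 0 were lower and 5 did not pass, with 21 higher when adjusted over the list alone. Csf1r, the receptor for macrophage growth factor, rose from 89.4 ± 12.5 to 160 ± 31.5 CPM (0.84, n = 3 each), the lysozyme gene Lyz2 rose by 0.94, Cd68 by 0.93 and the monocyte chemokine receptor gene Ccr2 by 1.22. The median was 0.91 (camera adjusted p = 4e-24), and adjusted p = 0.785 with an estimated correlation (camera unadjusted p = 0.0412). Many BaCl2 lists share this adjusted value, and only this list had an unadjusted p under 0.05. Of 8 neutrophil markers 2 were higher (Trem1 1.72, Csf3r 1.16), 1 was lower (Mmp9 -0.51) and 5 did not pass (5 higher and 1 lower when adjusted over the list alone, median 1.12, camera adjusted p = 0.00206). Of 11 Schwann cell markers, of the glia along nerves, 4 were higher (among them Erbb3 1.59, Mbp 1.09 and Ngfr 0.84), 0 were lower and 7 did not pass (7 higher when adjusted over the list alone, median 0.84, camera adjusted p = 0.000827). Of 15 endothelial markers none passed, with 13 positive (0 when adjusted over the list alone, median 0.45, camera adjusted p = 0.0037), and the camera call ended without WT library 2 (median 0.13, adjusted p = 0.0909). The neutrophil, Schwann cell and endothelial lists too had an adjusted p = 0.785 with an estimated correlation.

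Signalling genes split in the same BaCl2 libraries. Of 25 cytokine and chemokine genes, 3 were higher, 2 were lower and 20 did not pass (5 higher and 6 lower when adjusted over the list alone, camera adjusted p = 0.222). The inflammatory cytokine genes Il1b (1.13) and Tnf (0.98) rose, and Cxcl12 (-0.50) and Il6 (-0.42), both made by stromal cells, fell. Of 26 interferon response genes, 0 were higher, 3 were lower (among them Bst2 -0.56 and Stat2 -0.51) and 23 did not pass (3 lower when adjusted over the list alone). Their median was -0.36 (camera adjusted p = 2.44e-06, and adjusted p = 0.785 with an estimated correlation), and it was 0.01 with SMA libraries 1 and 2 left out. In complement, C3ar1 rose (1.06) and 11 of 12 members did not pass (1 higher when adjusted over the list alone, camera adjusted p = 0.272). In the Notch list Lfng rose (0.64) and 13 of 14 did not pass (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.483), and in the Wnt list Sfrp2 fell (-0.35) and 20 of 21 did not pass (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.645). Of 14 Hedgehog genes, Timp3 rose (0.43), Gli3 fell (-0.31) and 12 did not pass (3 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.514).

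Cholesterol synthesis and stress genes also moved after BaCl2. Of 21 cholesterol synthesis genes, 0 were higher, 3 were lower (Hmgcs1 -0.47, Sc5d -0.37, Stard4 -0.32) and 18 did not pass, with 9 lower when adjusted over the list alone and all 21 below 0 (median -0.24, camera adjusted p = 5.62e-08). Of 21 genes of the unfolded protein and integrated stress responses, 3 were higher (Sdf2l1 0.98, Creld2 0.58, Manf 0.40), 0 were lower and 18 did not pass (4 higher when adjusted over the list alone, median 0.10, camera adjusted p = 0.00838). Of 26 glycolysis and hypoxia genes, Vegfa rose (0.27) and 25 did not pass (4 higher when adjusted over the list alone, median 0.15, camera adjusted p = 0.000126). Of 27 oxidative phosphorylation genes, Ndufa1 fell (-0.29) and 26 did not pass (0 when adjusted over the list alone, median -0.06, camera adjusted p = 0.0329). Of 31 cell cycle genes, Mcm3 rose (0.43) and 30 did not pass (3 higher when adjusted over the list alone, median 0.07, camera adjusted p = 0.0028). Of 25 p53 targets, 3 were higher (Pmaip1 0.41, Cdkn1a 0.36, Mdm2 0.33), 0 were lower and 22 did not pass (3 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.526). Every list of this paragraph that passed camera had an adjusted p = 0.785 with an estimated correlation.

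Of the other lists kept as checks after BaCl2, ribosomal protein genes were lower by camera with 0 of 27 passing (0 when adjusted over the list alone, median -0.08, adjusted p = 3.52e-05), and so were dissociation and immediate early genes with 0 of 18 passing (0 when adjusted over the list alone, median -0.08, adjusted p = 0.0332). Both had an adjusted p = 0.785 with an estimated correlation. Lymphocyte markers (Il7r higher of 8, 1 higher when adjusted over the list alone, camera adjusted p = 0.526), satellite cell markers (Des and Vcam1 lower of 12, 2 lower when adjusted over the list alone, adjusted p = 0.588) and pericyte and smooth muscle markers (Rgs5 higher, Des and Acta2 lower of 13, 4 higher and 3 lower when adjusted over the list alone, adjusted p = 0.619) did not pass camera. Neither did myofibre (0 of 16, adjusted p = 0.762), tenocyte (0 of 10, adjusted p = 0.483) and mitochondrially encoded genes (0 of 13, adjusted p = 0.928), all at 0 when adjusted over the list alone. The erythroid and sex-linked lists had 3 and 4 genes tested, too few for camera, and 0 of them passed.

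After glycerol, the SMA libraries had more transcript of macrophage genes and of the antigen presentation genes among the largest changes. They had less of cholesterol synthesis and endothelial genes. These antigen presentation genes, for which no list was fixed, were H2-Aa (log2 fold change 1.89, SE 0.23), Cd74 (1.74, SE 0.21), H2-Eb1 (1.58, SE 0.22) and H2-Ab1 (1.45, SE 0.23). Pltp, which moves lipids between lipoproteins (1.78, SE 0.22), Rgs1 (1.47, SE 0.28) and Ms4a4c (1.43, SE 0.22) rose too. Apoe rose from 41782 ± 4544 normalized counts in WT to 120161 ± 45874 in SMA libraries (1.43, SE 0.28, n = 4 each, adjusted p = 0.0374). The falls were led by the endothelial genes Adgrf5 (-0.95, SE 0.16) and Cdh5, which encodes VE-cadherin (-0.93, SE 0.19), by Zfp469 (-0.74, SE 0.07), by smooth muscle actin, Acta2 (-0.70, SE 0.13), and by genes of cholesterol synthesis and transport. Of these Sqle, squalene epoxidase, fell from 7865 ± 586 to 4971 ± 763 normalized counts (-0.67, SE 0.11, n = 4 each, adjusted p = 0.0307). Cyp51 (-0.66), Stard4 (-0.65) and Idi1 (-0.64) fell as well.

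In total limma called 411 of 14330 genes after glycerol, 243 higher and 168 lower, and 139 of them had an absolute log2 fold change of at least 1 (115 higher, 24 lower). The genotypes did not overlap at 14.1% of the genes, where chance gives 2.86%. The authors' deposited table calls 1759 genes (1025 higher, 734 lower), among them all 411 called here, and its log2 fold changes correlate with those here across genes at 0.971. The limma count was 3 without SMA library 1, 0 without SMA library 2, SMA library 4, WT library 1 or WT library 3, 1645 without SMA library 3, 3 without WT library 2 and 82 without WT library 4. In these limma fits 2531 to 4095 genes had an unadjusted p under 0.05, against 3333 with all libraries. None of the 16 genes named for the size of their change, and none of the 18 passing genes named from the lists, passed with each library left out in turn.

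**Figure D2:**
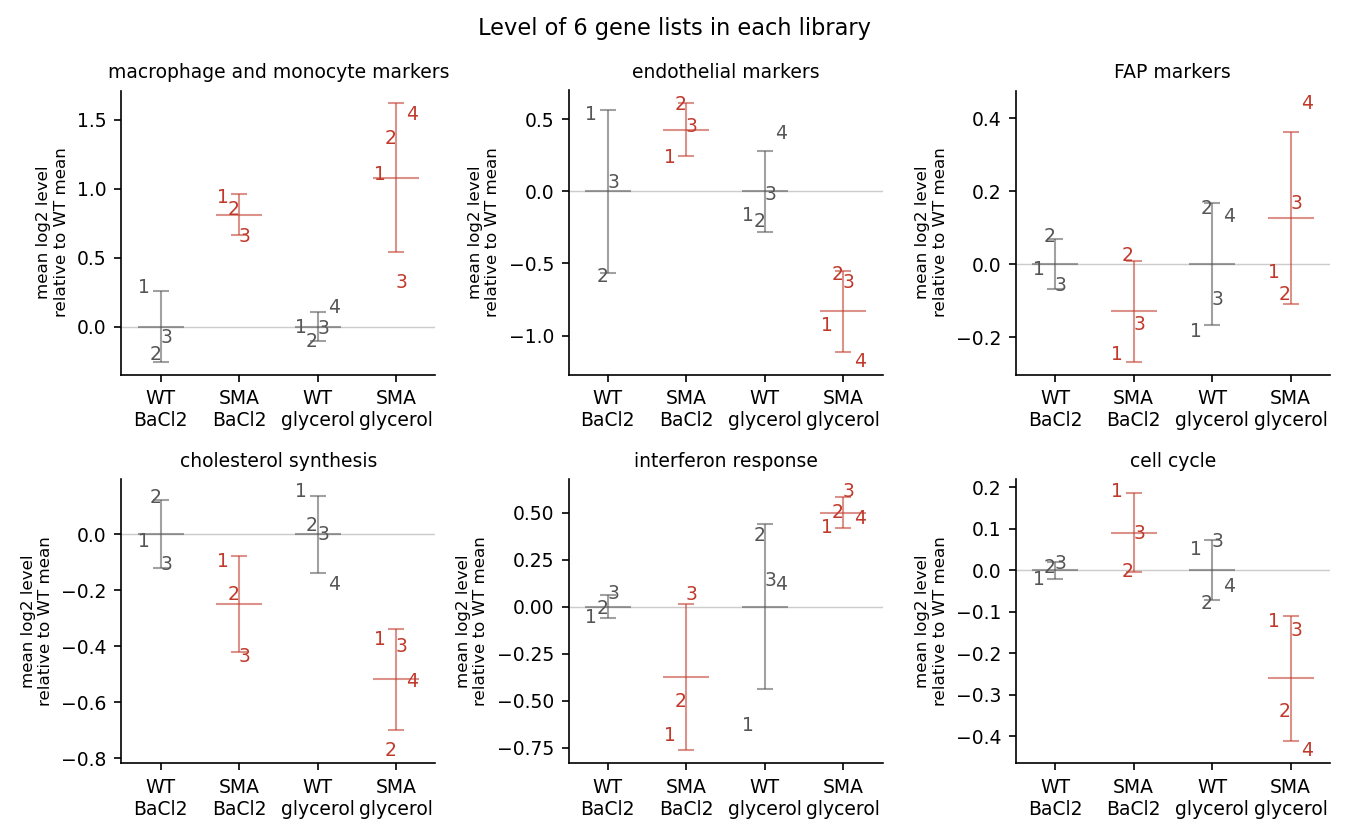
Mean log2 level of 6 gene lists in each library relative to the WT mean of the same injury (y axis); digits are replicate numbers, the horizontal line is the group mean and the bar is the SD, in grey for WT and red for SMA libraries (n = 3 per genotype after BaCl2, n = 4 after glycerol). SMA libraries lie above all WT libraries for macrophage markers after both injuries, and below them for endothelial, cholesterol synthesis and cell cycle genes after glycerol.

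The genes of fat formation again moved in different directions after glycerol. Of 23 adipogenic transcription factors 1 was higher (Nr1h3, which encodes the sterol sensor liver X receptor alpha, 0.61, adjusted p = 0.0395), 0 were lower and 22 did not pass, with 3 higher when adjusted over the list alone. Pparg stood at 1515 ± 209 normalized counts in SMA and 1059 ± 289 in WT libraries (0.55, SE 0.19, n = 4 each, limma adjusted p = 0.134), and Cebpa at 6665 ± 849 and 4709 ± 648 (0.50, SE 0.11, adjusted p = 0.052). The list was higher by camera, with a median of 0.11 (adjusted p = 0.0297), and adjusted p = 0.481 with an estimated correlation. Macrophage markers rose in the same libraries (median 1.05), so this rise cannot be assigned to FAPs here. Of 31 genes of adipocytes and lipid storage 2 were higher (Apoe and the lipoprotein lipase gene Lpl, 0.44, adjusted p = 0.0454), 4 were lower and 25 did not pass, and adjusted over the list alone 7 were higher and 7 lower. The 4 that fell were Fabp4 (-0.58), which is also 1 of the endothelial markers that fell, the fatty acid desaturase gene Scd1 (-0.46), the fatty acid synthase gene Fasn (-0.45) and Me1 (-0.26). The fat cell genes Adipoq, at 28.2 ± 16.8 normalized counts in SMA and 6.44 ± 3.24 in WT (1.83, SE 0.56, n = 4 each, limma adjusted p = 0.101), and Plin1, at 192 ± 126 and 53.7 ± 45.7 (1.96, SE 0.74, adjusted p = 0.156), did not pass. In the authors' deposited table Cebpa (0.50, adjusted p = 0.00199) and Adipoq (2.12, adjusted p = 0.0162) pass as higher, and Pparg (adjusted p = 0.06) and Plin1 (adjusted p = 0.121) do not. The list as a whole did not pass camera (median 0.07, adjusted p = 0.568), and the mean over its members was 0.38. FAP markers did not pass (0 of 25, 0 when adjusted over the list alone, median 0.10, camera adjusted p = 0.692), with Pdgfra at -0.10 (adjusted p = 0.534).

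Cholesterol synthesis genes fell together after glycerol. Of 21 tested, 0 were higher, 12 were lower and 9 did not pass, with 20 lower when adjusted over the list alone and all 21 below 0. Besides Sqle, Cyp51, Stard4 and Idi1 these included Msmo1 (-0.64), Hsd17b7 (-0.61), Sc5d (-0.60), Hmgcs1 (-0.59), Insig1 (-0.54), Fdft1 (-0.53) and Srebf2 (-0.37), which encodes the transcription factor that drives the pathway. The median was -0.55 (camera adjusted p = 1.27e-16), and adjusted p = 0.355 with an estimated correlation. In the same libraries macrophage markers were higher, with a median of 1.05, and endothelial markers lower, with a median of -0.90.

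Leukocyte and vessel genes moved apart after glycerol. All 24 macrophage and monocyte markers had a positive fold change, 11 were higher, 0 were lower and 13 did not pass, with 23 higher when adjusted over the list alone. Csf1r rose from 6476 ± 771 to 14060 ± 4485 normalized counts (1.06, n = 4 each), Ccr2 rose by 1.15 and Ptprc, the pan-leukocyte gene for CD45, by 1.22. Camera gave an adjusted p = 1.09e-16, and adjusted p = 0.355 with an estimated correlation. The mean level of the list was 1.10, 1.36 and 1.54 in SMA libraries 1, 2 and 4 and 0.32 in SMA library 3, relative to the WT mean. Of 15 endothelial markers, 0 were higher, 6 were lower (Tie1 -1.09, Esam -1.04, Cdh5 -0.93, Flt1 -0.90, Egfl7 -0.65, Fabp4 -0.58) and 9 did not pass, with all 15 lower when adjusted over the list alone (camera adjusted p = 2.93e-12, and adjusted p = 0.355 with an estimated correlation). Of 6 lymphocyte markers Cd4 rose (1.29) and 5 did not pass (2 higher when adjusted over the list alone, median 0.56, camera adjusted p = 0.0258). Of 12 pericyte and smooth muscle markers Acta2 fell and 11 did not pass (3 lower when adjusted over the list alone, median -0.24, camera adjusted p = 0.0258). Of 18 dissociation and immediate early genes Egr1 (0.59) and Dusp1 (0.34) rose and 16 did not pass (8 higher when adjusted over the list alone, median 0.15, camera adjusted p = 0.00229). These 3 lists had an adjusted p = 0.355 with an estimated correlation. Of 8 neutrophil markers Csf3r rose (1.22) and 7 did not pass (2 higher when adjusted over the list alone, camera adjusted p = 0.14).

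As lists, interferon response genes were higher and cell cycle genes lower after glycerol by camera, with few members that passed alone. Of 26 interferon response genes, 1 was higher (Irf9 0.37), 0 were lower and 25 did not pass, with 12 higher when adjusted over the list alone and all 26 above 0 (median 0.47, camera adjusted p = 1.85e-09, and adjusted p = 0.481 with an estimated correlation). The rise leaned on WT library 1, at -0.63 against 0.12 to 0.38 in the other WT libraries, and the median was 0.28 without it. Of 31 cell cycle genes, 0 were higher, 1 was lower (Foxm1 -0.31) and 30 did not pass, with 22 lower when adjusted over the list alone (median -0.29, camera adjusted p = 4.98e-12, and adjusted p = 0.395 with an estimated correlation). The proliferation marker Mki67 stood at -0.36 (adjusted p = 0.052). SMA libraries 2 and 4, with the highest macrophage levels (1.36 and 1.54), had the lowest cell cycle levels (-0.34 and -0.43), and with the macrophage level as a covariate, which shares the genotype effect, the cell cycle median was -0.06 with 10 of 31 positive. In oxidative phosphorylation Uqcrq fell (-0.27) and 26 of 27 did not pass (3 lower when adjusted over the list alone, median -0.08, camera adjusted p = 0.000556, and adjusted p = 0.395 with an estimated correlation). Of 32 matrix genes Tgfbi rose (0.51), Acta2 fell and 30 did not pass (1 higher and 1 lower when adjusted over the list alone, median -0.12, camera adjusted p = 0.0297, and adjusted p = 0.673 with an estimated correlation). The stress response list had 0 of 21 passing (1 higher and 7 lower when adjusted over the list alone, median -0.05, camera adjusted p = 0.0307, and adjusted p = 0.604 with an estimated correlation), and without SMA library 2 its median was 0.01. Ribosomal protein genes had 0 of 27 passing (0 when adjusted over the list alone, median -0.05, camera adjusted p = 0.0149, and adjusted p = 0.673 with an estimated correlation).

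Of 25 cytokine and chemokine genes Il1b rose after glycerol (1.26) and 24 did not pass (3 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.769), and of 20 Wnt genes Sfrp2 fell (-0.56) and 19 did not pass (1 higher and 3 lower when adjusted over the list alone, adjusted p = 0.982). The remaining lists had no member past the test and no camera call. They were the Hedgehog (0 of 14, adjusted p = 0.91), Notch (0 of 14, 2 lower when adjusted over the list alone, adjusted p = 0.773), complement (0 of 12, adjusted p = 0.351), p53 (0 of 23, adjusted p = 0.549), glycolysis and hypoxia (0 of 26, adjusted p = 0.902), satellite cell (0 of 12, adjusted p = 0.714), myofibre (0 of 16, adjusted p = 0.633), Schwann cell (0 of 10, 3 higher when adjusted over the list alone, adjusted p = 0.692) and tenocyte lists (0 of 10, adjusted p = 0.485), with 0 when adjusted over the list alone where no count is given. The erythroid and sex-linked lists had 3 and 2 genes tested, too few for camera, and 0 passed. Mitochondrially encoded genes were not analysed here.

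**Figure D3:**
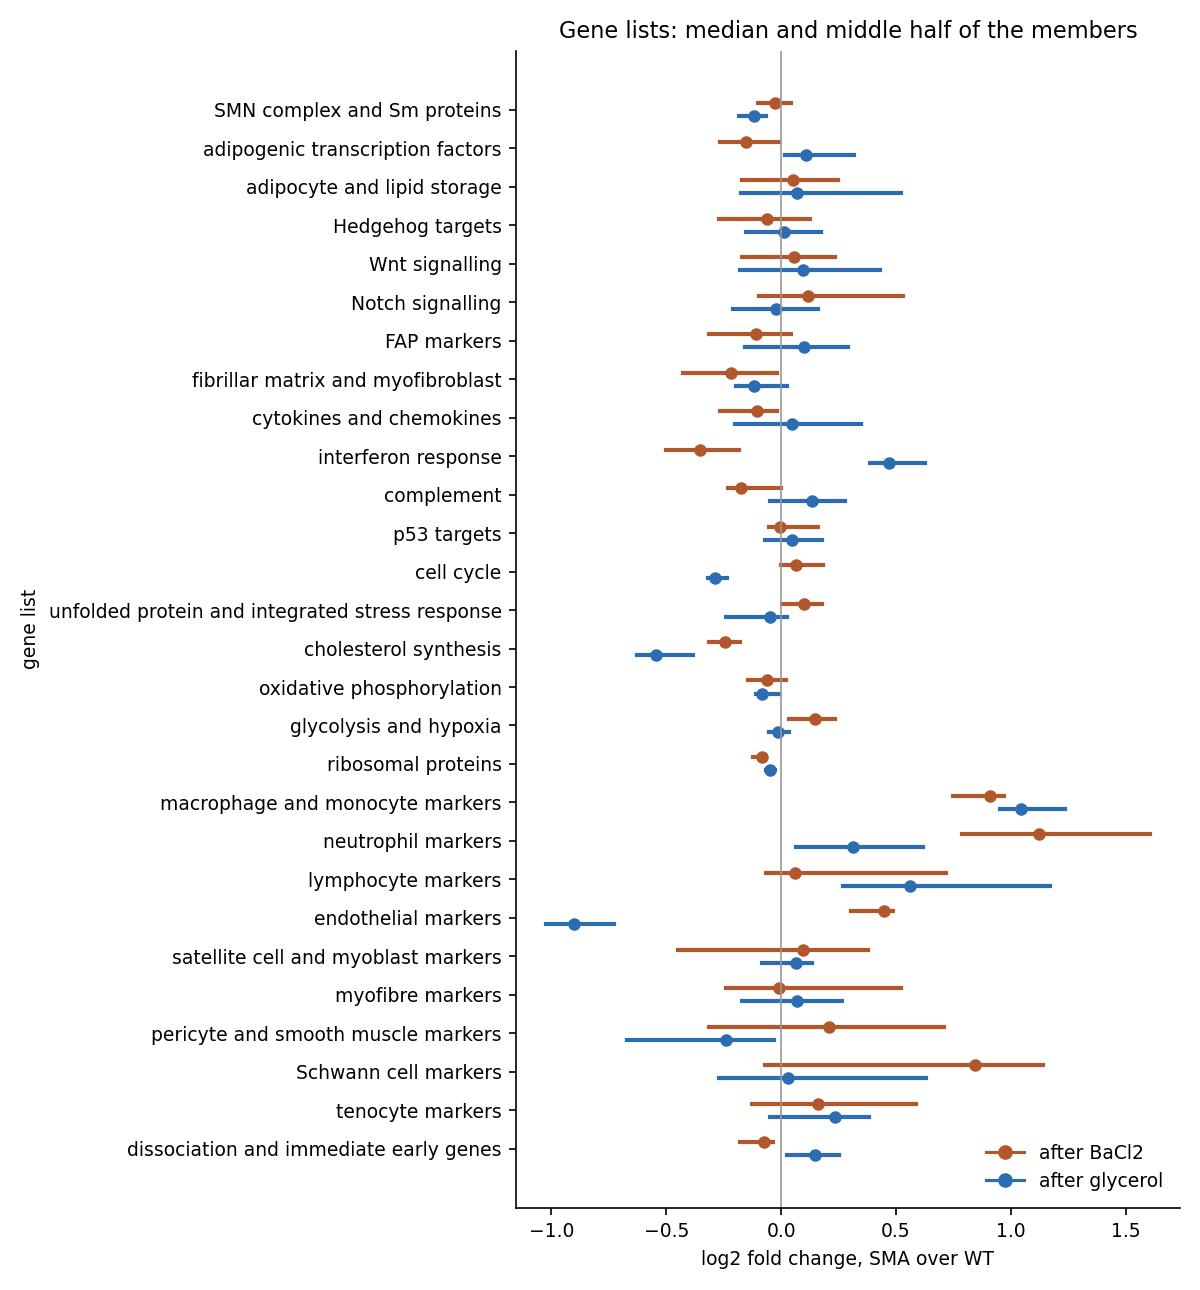
Log2 fold change of SMA over WT (x axis) for 28 gene lists with at least 5 members tested after both injuries (y axis), after BaCl2 (brown) and after glycerol (blue); dots are medians over the members and bars span their lower to upper quartile. Macrophage markers lie at medians of 0.91 and 1.05, and endothelial markers at 0.45 after BaCl2 and -0.90 after glycerol.

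Across lists, camera called 15 of 29 after BaCl2 and 14 of 28 after glycerol, and with an estimated correlation it called 0 in either (1 and 2 lists at an unadjusted p under 0.05). These were macrophage markers after BaCl2, and lymphocyte markers and immediate early genes after glycerol. An exact permutation of each list's mean level per library also called 0 after adjustment. After BaCl2 no list could go below p = 0.1, and after glycerol 11 lists reached the smallest possible exact p of 0.0286 (adjusted p = 0.078), among them the macrophage, endothelial, cholesterol synthesis, interferon, cell cycle and adipocyte lists. The level of the adipocyte list was 0.38 above WT after glycerol.

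Single libraries moved many of the list medians, while the macrophage and cholesterol synthesis lists kept theirs within 1.5 times and their camera calls after both injuries, as did the endothelial and cell cycle lists after glycerol. After BaCl2 the FAP marker median ran from -0.18 without SMA library 2 to -0.05 without WT library 2 (camera adjusted p = 0.0467), and the interferon median from -0.58 without SMA library 3 to -0.19 without SMA library 1. The endothelial median there ran from 0.13 without WT library 2 to 0.81 without WT library 1, and the cell cycle median from 0.02 without SMA library 1, where the call ended, to 0.14 without SMA library 2. The BaCl2 calls of the stress response, oxidative phosphorylation and immediate early lists ended without each of 3 libraries. After glycerol the SMN complex median ran from -0.17 without SMA library 3 to -0.08 without SMA library 4, and that of adipogenic transcription factors from 0.06 without WT library 1 to 0.16 without WT library 2. The glycerol call ended without each of 3 libraries for adipogenic transcription factors and for matrix genes, of 2 for lymphocyte markers and of 1 for pericyte markers and for ribosomal proteins, and the stress response call ended or turned without 5.

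The genotype effect differed between the injuries at 1470 of 13960 genes when the difference itself was tested, with 772 more positive and 698 more negative after glycerol. Endothelial, cell cycle, adipogenic and immediate early genes stood apart when the level of each list was tested. Endothelial markers moved from a median of 0.45 after BaCl2 to -0.90 after glycerol, and the list level differed by -1.26 (exact permutation p = 0.00571, adjusted p = 0.0428). Cell cycle genes differed by -0.35 (exact p = 0.00429, adjusted p = 0.0428), adipogenic transcription factors by 0.28 (exact p = 0.00286, adjusted p = 0.0428) and dissociation and immediate early genes by 0.27 (exact p = 0.00429, adjusted p = 0.0428). Interferon response genes differed by 0.87 (exact p = 0.0114, adjusted p = 0.0684), with 16 of 26 members more positive after glycerol, and did not pass by this test. Macrophage markers differed by 0.27 in list level (exact p = 0.671, adjusted p = 0.746), and camera on the difference gave an adjusted p = 0.0714. The relabelings shuffle the genotype within both injuries, so a large rise shared by the injuries (0.812 and 1.08) widens the differences they give. The exact test therefore cannot decide whether the macrophage rises differ.

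Among single genes, the antigen presentation gene H2-Aa was at 0.06 after BaCl2 and 1.89 after glycerol, a difference of 1.83 (SE 0.27, adjusted p = 4.68e-08). The interferon-induced genes Cxcl9 (-0.58 after BaCl2, 0.93 after glycerol) and Irf7 (difference 1.40), the growth factor gene Ptn (1.40) and Draxin (1.41) were also more positive after glycerol. Arg1 (-2.41), the chemokine gene Ccl6 (-1.61), the pericyte gene Rgs5 (-1.60), Cdh5 (-1.54) and Srp54b (-1.76) were more negative. Srp54b has near-identical copies, so its value is uncertain. The z test behind these counts takes the standard errors as known and was liberal on simulated data, with 24% of its calls false against 7.88% for a t reference with Satterthwaite degrees of freedom. With that reference 530 genes passed (262 more positive, 268 more negative), and of the 10 genes named all but Srp54b (adjusted p = 0.0718) passed.

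SMA effects shared by the injuries were mostly rises. Of the genes tested in both, 85 were higher after both injuries where independent lists would share 9 (Fisher's exact test across genes, p = 1.33e-60), and 77 remained without the macrophage, neutrophil and lymphocyte lists, where 8.17 would be shared (p = 1.5e-54). They include Apoe, Il1b, Ccr2, Csf1r, Ptprc, Cd14 and Csf3r. Only 7 genes were lower after both, where 3.68 would be shared (Fisher's exact test p = 0.1). These included Smn1, the cholesterol synthesis and transport genes Hmgcs1, Sc5d and Stard4, the Wnt inhibitor gene Sfrp2, and Acta2. Across the 13960 genes the log2 fold changes of the injuries correlated at 0.246 (Pearson) and 0.121 (Spearman), and genes are not independent replicates. The shared rises numbered 66, 25 and 97 without BaCl2 SMA library 1, 2 or 3 and 89, 31 and 8 without BaCl2 WT library 1, 2 or 3. They numbered 1 and 359 without glycerol SMA library 1 or 3, 18 without glycerol WT library 4, and 0 without each of the other 5 glycerol libraries.

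**Figure D4:**
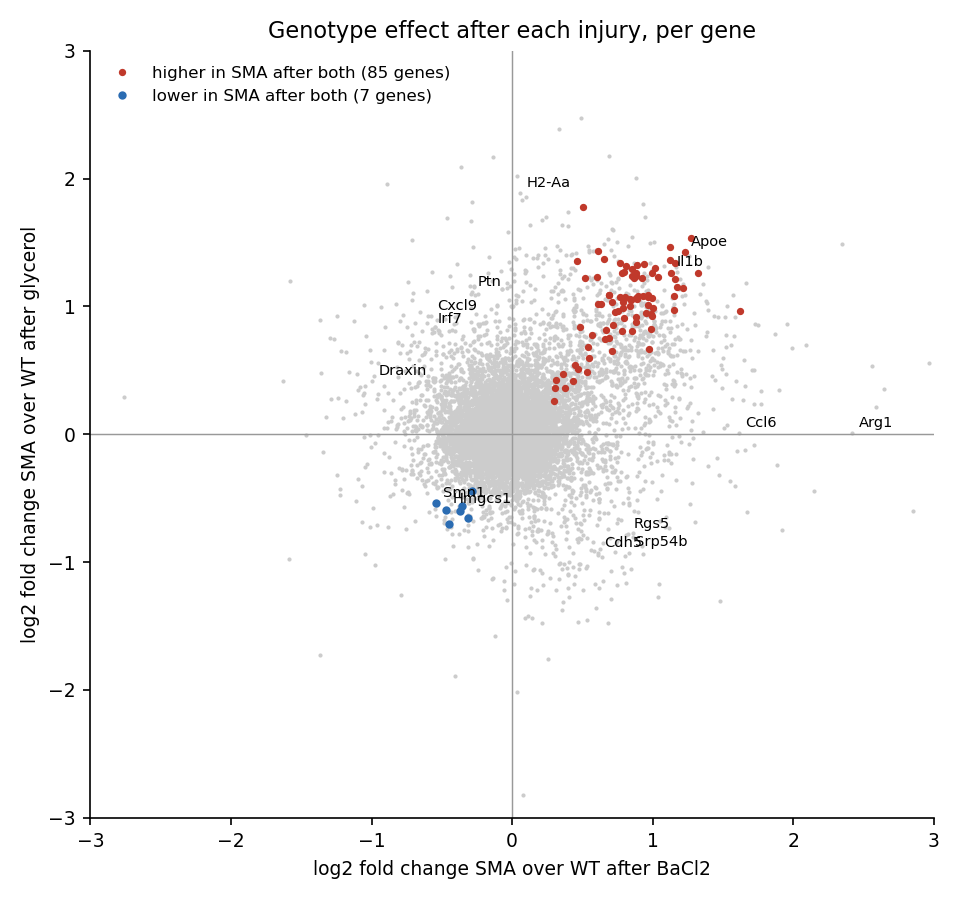
Log2 fold change of SMA over WT after BaCl2 (x axis) and after glycerol (y axis) for each gene tested in both; red dots are the 85 genes higher after both injuries, blue dots the 7 lower after both, grey dots all other genes, and 6 genes lie outside the axes. The shared rises lie along the diagonal, with Apoe at 1.23 and 1.43, and Arg1 and Ccl6 lie far right at values near 0 after glycerol.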

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

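The test of endothelial cells and the regroupings of libraries were planned before the data were examined, and all other tests of explanations here were chosen only after the results were seen.

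Macrophage and monocyte genes were higher in the SMA libraries after BaCl2 (19 of 24 passing, median 0.91, adjusted p = 0.785 with an estimated correlation) and after glycerol (11 of 24 passing, median 1.05, adjusted p = 0.355 with an estimated correlation). After glycerol, a lower share of FAPs that raises every other cell type alike was excluded as the whole cause. Macrophage markers lay 1.95 above endothelial markers there, with the middle ranges of the members apart. After BaCl2 macrophage markers lay 0.812 above satellite cell markers, with the middle ranges apart too. The satellite cell list holds Vcam1, also a FAP marker, and Des, also a pericyte marker, so it does not stand for a single cell type. The neutrophil (1.12), Schwann cell (0.84) and endothelial medians (0.45) were positive after BaCl2 as well. A lower share of FAPs was therefore not excluded there and may account for part or all of the rise. More macrophages in SMA muscle at this time, more leukocytes carried along by the magnetic sort, and FAPs that express these genes were not tested against each other and stay open. Rises of Apoe, Plin2, Fabp5, Cd36 and Spp1, which macrophages express too, therefore cannot be assigned to FAPs here.

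Cholesterol synthesis genes were lower after glycerol, with 12 of 21 passing, 9 not, and a median of -0.55 (adjusted p = 0.355 with an estimated correlation). Dilution of FAP transcripts by leukocyte RNA was excluded, since FAP markers lay 0.645 above the cholesterol synthesis genes. The scaling of the libraries moves every gene alike, so it cannot set the list apart from other genes. The list median lay 0.546 below that of all genes. The upper quartile of the list (-0.39) lay below the lower quartile of all genes (-0.11). Normalization centres the genes as a whole, so only a fall relative to other genes is shown. Fewer endothelial cells could account for the fall only if they supplied 67.8% of the cholesterol synthesis transcripts in WT, which is left open.

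After BaCl2, 12 genes were more than 3 times higher in SMA libraries 1 and 2 than in each other library, while the highest number for any other pair of libraries was 1. Gm13394 stood at 325 and 68.2 CPM there and at 4.68 CPM or less elsewhere, and Pianp, Hal, C1rb, H2-Q1 and Il36g are among the others. A single linked segment of the genome was excluded, as the genes lie on 7 chromosomes. Reads shared with a parent gene may play a part, as 6 of the 12 are annotated as pseudogenes, and this is left open. A different genetic background of the mice behind these libraries could also give such a pattern, and was not tested.

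Regrouping the libraries gave the following. After glycerol 1 of 35 splits, the real one, called as many genes, with 411 against 2 for the highest other. That is the smallest share that 35 splits allow, so chance was made less likely but not excluded. After BaCl2 the real split called 863 genes and the highest other 0, and 1 of 10 splits is too few to exclude chance. For the difference between injuries 1 of 100 drawn relabelings, the real one, reached 1470 genes, and the highest other reached 1371. That relabeling kept the real BaCl2 groups and regrouped the glycerol libraries, and another with neither injury's real groups reached 790. The size of the count therefore does not measure the size of the difference. Relabeling also removes a genotype effect that the injuries share, so it cannot exclude chance for the difference itself.

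The genotype effect differed between the injuries at 1470 genes. By camera the median difference was 0.314 for adipogenic transcription factors (exact permutation adjusted p = 0.0428), 0.314 for FAP markers (0.393), 0.831 for interferon response genes (0.0684), -0.366 for cell cycle genes (0.0428), -0.284 for stress response genes (0.153), -0.248 for cholesterol synthesis (0.568), -0.179 for glycolysis and hypoxia (0.578), -1.31 for endothelial markers (0.0428) and 0.25 for dissociation and immediate early genes (0.0428), so 4 of these 9 lists passed the exact test. A list whose genotype effect is shared by the injuries, such as cholesterol synthesis, may differ and still not pass the exact test. Among single genes the differences were 1.83 for H2-Aa, 1.501 for Cxcl9, 1.41 for Draxin, 1.40 for Ptn, 1.40 for Irf7, -2.41 for Arg1, -1.76 for Srp54b, -1.61 for Ccl6, -1.60 for Rgs5 and -1.54 for Cdh5.

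Single libraries far from the others of their group were sought by Dixon's ratio after glycerol, where a group has 4 libraries, and not after BaCl2. They were found in 11 of 232 groups, where 1 in 20 gives 11.6 by chance. They were H2-Eb1 in SMA library 3 (1368 against 2653 to 2748), Ms4a4c in WT library 1 (608 against 1069 to 1132), Stard4 in WT library 4 (5372 against 6482 to 6704), Nr1h3 in SMA library 3 (857 against 1168 to 1220), Srebf1 in SMA library 2 (3863 against 4369 to 4410), Scd1 in WT library 1 (12160 against 10390 to 10600), Hes1 in SMA library 3 (7925 against 9521 to 9575), Has2 in SMA library 4 (20350 against 27740 to 28780) and C1s1 in SMA library 3 (48550 against 38660 to 39750). The level of the stress response list was -0.11 in WT library 2 (0.03 to 0.04 in the others), and that of the myofibre list was 0.77 in SMA library 1 (-0.19 to -0.04 in the others). SMA library 3 holds 4 of these 11 values and also the lowest macrophage level of the SMA libraries.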

How the results depend on the processing

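The alternatives added after the data were seen are the ones with SMA libraries 1 and 2 left out, the macrophage covariate, the rescaling, the t reference, the shared calls without the immune lists (77 higher, 7 lower) and the permutation of list levels. The cause of a change was not tested unless given.

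After BaCl2, 863 genes became 1687 with DESeq2 and 1867 with no filter, 108 without SMA libraries 1 and 2 (the lone SMA library was assumed to vary like the WT libraries), 0 by edgeR with the macrophage covariate (813 at an unadjusted p under 0.05), 169 at an absolute log2 fold change of at least 1, and 41 to 1577 with single libraries left out. After both injuries the macrophage level separates the genotypes (after glycerol the lowest SMA library is at 0.32 and the highest WT library at 0.14), so that covariate takes up part of the genotype effect itself and excludes nothing. After glycerol, 411 became 201 above the median mean, 4 with the covariate, 139 at a log2 fold change of at least 1, and 0 to 1645 with single libraries left out (limma, 2531 to 4095 at an unadjusted p under 0.05). The difference count of 1470 became 958 with DESeq2, 586 without SMA libraries 1 and 2, 60 with the covariate, 530 with the t reference and 257 at a difference of at least 1.

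Shared rises (85) became 271 at an adjusted p under 0.1 and 0 under 0.01, and 0 to 359 with single libraries left out. Shared falls (7) became 32 and 0, and 0 to 18. Lists called after BaCl2 (15) became 7 with the covariate and 0 with an estimated correlation, fry in one direction or exact permutation, and 18 with fry in mixed directions. After glycerol (14) they became 0 with an estimated correlation, 7 with fry in one direction, 18 in mixed directions, 0 with exact permutation and 8 without SMA library 3. Smn1 after BaCl2 (-0.54) was -0.59 to -0.46 with single libraries left out, -0.51 without SMA libraries 1 and 2 (adjusted p = 0.106) and -0.46 with the covariate (0.997). After glycerol (-0.54) it was -0.61 to -0.47 and -0.67 with the covariate (0.283).

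Directions turned with the covariate after BaCl2 for adipogenic transcription factors (0.0381), FAP markers (0.0561), matrix (0.101), interferon response (0.233), glycolysis and hypoxia (-0.096), neutrophil (-0.276) and endothelial markers (-0.783). So they did for Pianp (-0.52), Arg1 (-0.68), Plin2 (-0.0172), Fabp5 (-0.16), Cd36 (-0.54), Sfrp2 (0.0134), Lfng (-0.0707), Lum (0.00578), Il1b (-0.14), Bst2 (0.13) and Cdkn1a (-0.0524), for the difference of Cxcl9 (-0.28), and by construction for macrophage and monocyte markers after glycerol (-0.165). Interferon response turned to 0.0116 without SMA libraries 1 and 2, and unfolded protein and integrated stress response after glycerol to 0.00661 without SMA library 2 (range from -0.0917 without SMA library 4).

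With a replicate block, counts were 1144 after BaCl2, 257 after glycerol and 1940 for the difference, lists 14 and 14, and Smn1 after glycerol -0.54 (adjusted p = 0.0715). Libraries of the same number correlated at -0.126 to 0.087, which gives no sign that the numbers pair samples. With so few libraries per group such correlations cannot exclude a pairing, and the labels do not state one, so it is left open.

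DESeq2, other factors and count filters were not run for glycerol, which has no counts, nor pseudocounts for BaCl2. With the covariate the glycerol medians went from -0.29 to -0.06 for cell cycle genes (10 of 31 positive) and from -0.55 to -0.29 for cholesterol synthesis (0 of 21 positive). What depth allows after glycerol is unknown.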

Other observations

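The liver X receptor test and the reading of shared genes below were chosen only after the results were seen. After both injuries the SMA libraries held more Apoe, Abca1, Abcg1 and Pltp, which serve the export and transfer of sterols and phospholipids. The log2 fold changes were 1.23, 0.69, 0.46 and 0.50 after BaCl2 and 1.43, 0.75, 1.35 and 1.78 after glycerol. Hmgcs1, Sc5d and Stard4 were lower after both. The fat cell genes did not move together with these, as Fasn (-0.45) and Scd1 (-0.46) fell after glycerol while Pparg, Cebpa, Adipoq and Plin1 had positive fold changes that did not pass with limma. The authors' deposited table calls Adipoq (2.12, adjusted p = 0.0162) and Cebpa (0.50, adjusted p = 0.00199) higher after glycerol, so whether these 2 pass depends on the test.

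After glycerol 6 of 15 endothelial genes fell (list adjusted p = 0.355 with an estimated correlation, exact permutation adjusted p = 0.078). The list level differed by -1.26 from that after BaCl2 (exact permutation adjusted p = 0.0428), and H2-Aa rose, with a difference of 1.83. As the injury is also the batch, this could come from either.

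One hypothesis is that cells of SMA muscle carry excess sterol, which activates the liver X receptors and lowers synthesis through SREBP2. Of 11 receptor targets other than Apoe, Abca1, Abcg1 and Pltp, which prompted the test, 3 (Nr1h3, Mylip and Lpl) were higher and 2 (Fasn and Scd1) lower after glycerol, and 1 (Mertk) was higher after BaCl2. This leaves the hypothesis open. The receptors raise Fasn and Scd1, so their falls are not what active receptors alone would give. Whether excess sterol lowers these genes by another route was not tested. Macrophages clearing debris express the same export genes, and their markers rose in the same libraries (1.05 after glycerol). The rise of the export genes might therefore come from macrophages alone. This does not cover the fall of the synthesis genes after glycerol, for which dilution by leukocyte RNA was excluded above. Sterol levels, or the same genes in single cells, would tell these apart.

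The lean towards fat named in the series title was not seen as a rise of the adipocyte list, whose median was 0.05 after BaCl2 and 0.07 after glycerol, although its mean level after glycerol was 0.38 above WT with no overlap of the genotypes (exact permutation p = 0.0286, adjusted p = 0.078). The adipogenic transcription factors were higher after glycerol (0.11) and lower after BaCl2 (-0.15) by camera, and neither passed with an estimated correlation. This may be a matter of power, since Adipoq, which passes in the authors' deposited table, stood at 1.83 and Plin1 at 1.96 after glycerol with a wide spread between libraries and the limma count of 411 was 0 without any of 4 libraries. At 3 days after injury mature fat cell genes may also not yet be expressed, which was not tested.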
